A study of Mus musculus with 2 samples.

How the data were processed

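Lung CD4+ cells of mice were measured by droplet single-cell RNA sequencing in 2 libraries, 1 labelled Nfe2l2fl/fl control and 1 labelled Cd4cre Nfe2l2fl/fl. In the Cd4cre mouse, Cre recombinase is made under Cd4 regulatory sequences, and the loxP-flanked (fl) gene, Nfe2l2, encodes the transcription factor NRF2. Per the labels the libraries were made with 10x Genomics 5' reagents (version 2 chemistry), the mice were 8 to 15 weeks old, and tissue was taken 16 h after the last airway dose. The labels describe more than 1 airway model without saying which one these libraries come from, and give neither the number of mice per library, nor their sex, nor the exons flanked by loxP sites. The deposited matrices hold raw UMI counts (unit counts) per gene and barcode, with no normalization. The submitters' processing notes name Cell Ranger 4.0.0 and the genome build GRCm38, and Cell Ranger 4.0.0 is also in the file header. The annotation is not given in the sources used here. Of 32285 feature IDs in the matrices, 32158 were found in GENCODE mouse release 21, which supplied coordinates. The other deposited files of each library hold gene names and cell barcodes (unit other) in matrix order.

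Groups came from the sample titles. Barcodes with fewer than 500 genes or at least 10% mitochondrial UMIs were removed. Scrublet, run per library in scanpy 1.11.5, marked 28 (0.239%) of the cells that passed these filters. That is 2 cells (0.0368%) in the control library and 26 (0.412%) in the other. At the expected rates of 4.35% and 5.04% this caller has not worked, so doublets must be taken as present. An alternative removed the highest-scoring cells at those rates. Counts were scaled to 10000 per cell and logged for clustering on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1, over both libraries together and without integration. Genes of the compared lists, cytokine, TCR, immunoglobulin, mitochondrial, ribosomal and sex-linked genes were left out of the variable genes. Clusters were named from markers fixed before the data were examined. A marker counted at 2-fold or more over the other cells and at least 10 CPM (a gene's share of the UMIs summed in a library and cell class, on the usual CPM scale), and a name needed 3 markers. Details of the naming were set after seeing the data. NK and innate lymphoid markers do not bar a T cell name where T cell markers are high, which made cluster 8 Th1-like in place of NK-like. A cluster named for a T cell lineage stays unnamed where it has 5 or more markers of a second lineage, which keeps cluster 15 out of the named classes (0.693% of T cells in the control library and 0.71% in the other). Cycling and interferon-responsive states, which cut across lineages, were exempt, so cluster 5 kept its interferon-responsive name with 6 Th17 markers.

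Raw UMIs were summed per library and cell class. With 1 library per group no test was possible, and no paired analysis was possible because each group holds 1 library. Values are given for both libraries, with 95% intervals: exact Poisson for a CPM, Clopper-Pearson for a share, exact conditional binomial for a ratio of counts and Newcombe for a difference of shares. These cover counting error only, not the spread between mice or libraries. The 18 gene lists compared were fixed before the data were examined. A list is given as the median log2 ratio over members with at least 20 UMIs, with an order-statistic interval over genes and a percentile among 10000 random lists matched on expression, as a description of these libraries. Genes are not independent replicates. The typical gene lay slightly below 0, with a median log2 ratio of -0.031 in T cells and -0.039 in Th2-like cells. Those medians are over genes with at least 50 UMIs in each library. Counts of lower genes overstate a shift for that reason, and the percentile takes it into account. Shares of cells with a UMI were compared after thinning each cell to 2000 UMIs. Polyfunctional means a UMI of at least 2 of the 3 cytokine genes Il4, Il5 and Il13. Named genes followed a size rule, not a test. In all T cells and in Th2-like cells these were the 12 highest and 12 lowest log2 ratios of CPM with 10 CPM added, among genes with at least 50 CPM in a library. In other classes with at least 200 cells per library they were the 5 highest and 5 lowest. TCR, immunoglobulin, hemoglobin, mitochondrial, ribosomal protein and sex-linked genes and gene models were left out of this ranking. Of each list, up to 4 members by counts and up to 4 by size of change among those with at least 50 UMIs could be named. Genes named outside these rules are said to have been chosen after their values were seen.

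Alternatives covered the cell filter, doublets, clustering resolution, scaling and genes, a gate on UMIs in place of clusters, the scaling of counts, the weight of cells, the minimum count of list members and thinning. Added after seeing the data were removal by doublet score, thinning before clustering, leaving out cells with a leading Trbv20, and T cell clusters brought to the same makeup. The computation was checked on simulated data. Gene sums were drawn as Poisson counts at the levels of these libraries, which is the model that the ratio intervals assume. Coverage near 95% thus follows from that model. It leaves out spread between cells and the effects of clustering, so it does not show that the intervals suit these cells. Ratio intervals held the true value for 95.3% of 12521 unchanged genes in T cells and 95.7% of 10236 in Th2-like cells. Simulated folds of 0.5, 1.5 and 2 came back with medians of 0.503, 1.50 and 1.99 in T cells. Of 100 unchanged lists, 4 in T cells and 1 in Th2-like cells fell below the 2.5 percentile. Simulated cells of one makeup at different depths differed in polyfunctional share without thinning (80.5% against 98.6%) and were close after it (46.0% and 45.3%). Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9 were used.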

Results

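The transcriptomes of lung CD4+ cells were compared between 1 library labelled Nfe2l2fl/fl control and 1 labelled Cd4cre Nfe2l2fl/fl. The deposited design text states that single-cell sequencing was done to look for pathways that NRF2 controls in helper T cells. The control library held 5729 barcodes and 41391255 UMIs, with a median of 5996 UMIs and 2049 genes per barcode. The library labelled Cd4cre held 6808 barcodes and 38744058 UMIs, with medians of 4813 UMIs and 1730.5 genes. After filtering, 5431 and 6280 cells were used. There are no replicates, so every interval below covers counting error only and no difference was tested against the spread between mice.

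The cells formed 18 clusters, of which 11 were T cells. T cells made up 90.4% of the control library (4909 cells, interval 89.6 to 91.2) and 71.8% of the library labelled Cd4cre (4510 cells, 70.7 to 72.9). Their median depth was 6458 and 5636.5 UMIs. Clusters with macrophage markers such as Lyz2 and Chil3 took 7.24% and 24.7% of all cells, although the labels call the material CD4+ cells. Cluster 7, led by Chil3, Ccl6 and Lyz2 and named macrophage-like, held 3.96% and 7.85%. Cluster 6 carried 13 macrophage markers but was led by Tgfbi, Ccl24 and class II genes, stayed unnamed, and held 1.90% and 16.4%. The named T cell classes were Th2-like (Gata3, Il1rl1, Il17rb), Th1-like (Tbx21, Cxcr3, Ccl5), Th17-like (Ccr6, Il1r1), Treg-like (Foxp3, Ikzf2, Il2ra), naive or central memory-like (Ccr7, S1pr1), cycling-like (Mki67, Top2a) and interferon-responsive-like (Ifit1, Ifit3, Isg15, with the Th17 genes Il22 and Tmem176b also among its leading genes). The Tfh-like name rests on 3 markers, Sostdc1, Sh2d1a and Tbc1d4, and that cluster was led by Ccl1. T cell cluster 2, led by Ccr1 and Cpe, stayed unnamed.

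The level of the targeted gene was examined first, although the labels state a genotype and not a level. Nfe2l2 was higher, not lower, in T cells of the library labelled Cd4cre. It had 1219 UMIs (31.6 CPM, interval 29.8 to 33.4) in the control library and 5323 UMIs (173 CPM, 168 to 178) in the other, a log2 ratio of 2.45 (2.36 to 2.55), or 5.48-fold. The log2 ratio lay between 1.74 and 2.79 in the 8 T cell classes and clusters with at least 200 cells per library. In macrophage-like cluster 7 the levels were 118 and 135 CPM, a log2 ratio of 0.18 (-0.16 to 0.54). Other cells outside the T lineage did differ, with 112 and 199 CPM in cluster 6 and 57.2 and 193 CPM in dendritic cell-like cluster 12 (log2 1.75, 1.18 to 2.37). Nfe2l2 (ENSMUSG00000015839) lies on GRCm38 chromosome 2 from 75675513 to 75704641 on the minus strand, with 5 exons in its first annotated transcript. The deleted exons are not given in the labels and the reads come from transcript 5' ends, so these counts neither show nor exclude a deletion. Because these counts do not settle the genotype of either library, libraries are named below by their labels only. Each direction depends on those labels.

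**Figure D1:**
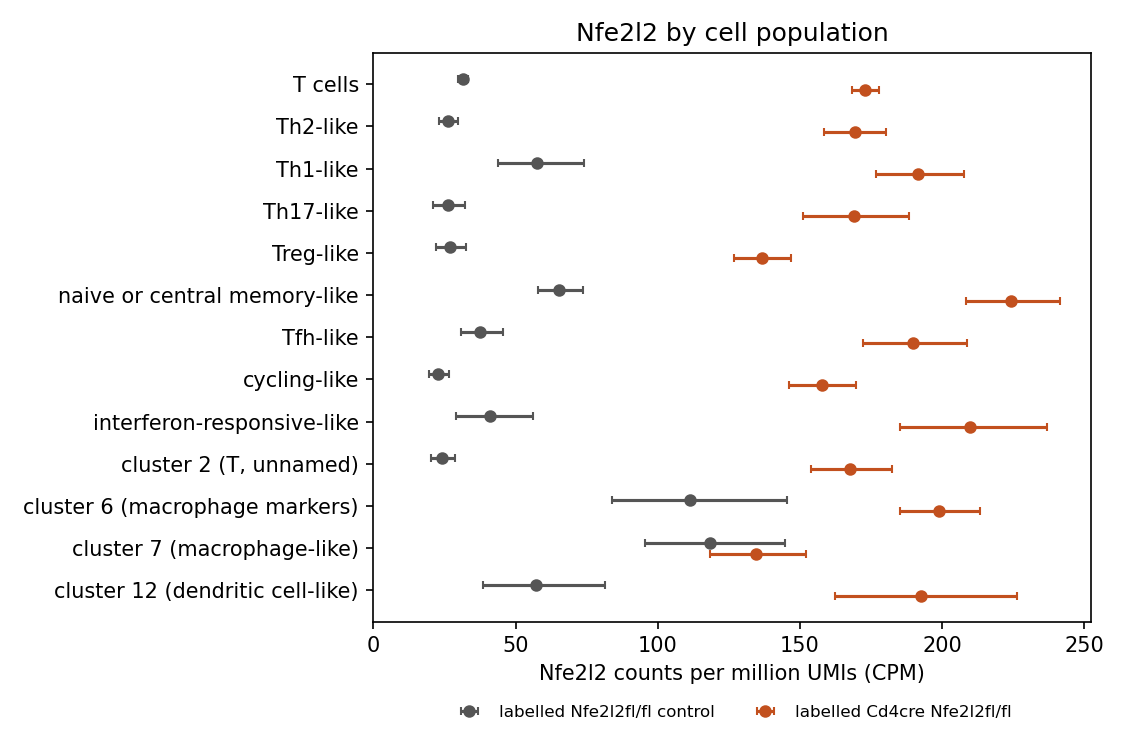
Nfe2l2 level in CPM (horizontal axis, linear) in all T cells, in T cell classes and in clusters 2, 6, 7 and 12, for the library labelled control (grey) and the library labelled Cd4cre (orange). Points are the 1 library of each group and bars are exact Poisson 95% intervals. All T cells stand at 31.6 and 173 CPM, and macrophage-like cluster 7 at 118 and 135 CPM.

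Genes known as NRF2 targets showed no shift as a list in T cells. Of 29 measured targets, 12 were higher and 17 lower in the library labelled Cd4cre, with a median log2 ratio of -0.04 (-0.17 to 0.04) at percentile 26.0 of random lists. Nqo1, a quinone reductase much used as an NRF2 readout, was lower, with 39 UMIs in the control library and 11 in the other (log2 -1.50, -2.61 to -0.51). Gclc, a subunit of the enzyme that limits glutathione synthesis, was at 41.7 and 35.5 CPM (log2 -0.23, -0.34 to -0.12). Prdx1, a peroxiredoxin, was at 469 and 416 CPM, and thioredoxin Txn1 at 406 and 384 CPM. Fth1, the ferritin heavy chain, went the other way, from 2901 to 3404 CPM (log2 0.23, 0.22 to 0.24). In Th2-like cells the median of 27 targets was -0.13 (-0.22 to 0.06) at percentile 2.17, with 18 lower. The other antioxidant genes had a median of -0.02 (-0.15 to 0.09) in T cells, with 5 of 16 higher. Among them were Sod1 (43.3 and 54.9 CPM) and Txnrd2 (27.6 and 23.2 CPM).

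The makeup of the T cells differed between the libraries. Th2-like cells were 20.9% of T cells (1027 cells, interval 19.8 to 22.1) in the control library and 15.4% (695 cells, 14.4 to 16.5) in the library labelled Cd4cre, a difference of -5.51 percentage points (-7.07 to -3.94). This direction depended on the clustering: with genes scaled within each library the difference was 1.35 points (-0.17 to 2.88), and at resolution 2 it was -2.15. Treg-like cells were 11.7% (10.8 to 12.7) and 18.4% (17.2 to 19.5), a difference of 6.63 points that kept its sign in all 11 alternatives. Th1-like cells were 4.62% (227 cells) and 14.6% (659 cells). That cluster also held 3 CD8 T cell markers. At resolution 0.5 no cluster was named Th1-like, so the difference has no value there. Th17-like cells were 8.15% and 5.34%, a direction that turned in 3 alternatives. Naive or central memory-like cells were 17.6% and 15.8%, Tfh-like cells 6.15% and 5.63%, cycling-like cells 8.78% and 6.76%, and interferon-responsive-like cells 3.24% and 4.99%. Unnamed T cells were 18.8% and 13.1%, of which cluster 2 held 18.1% and 12.4%. The libraries differed in depth and in their non-T cells, and 1 library per group cannot separate genotype from mouse or handling.

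**Figure D2:**
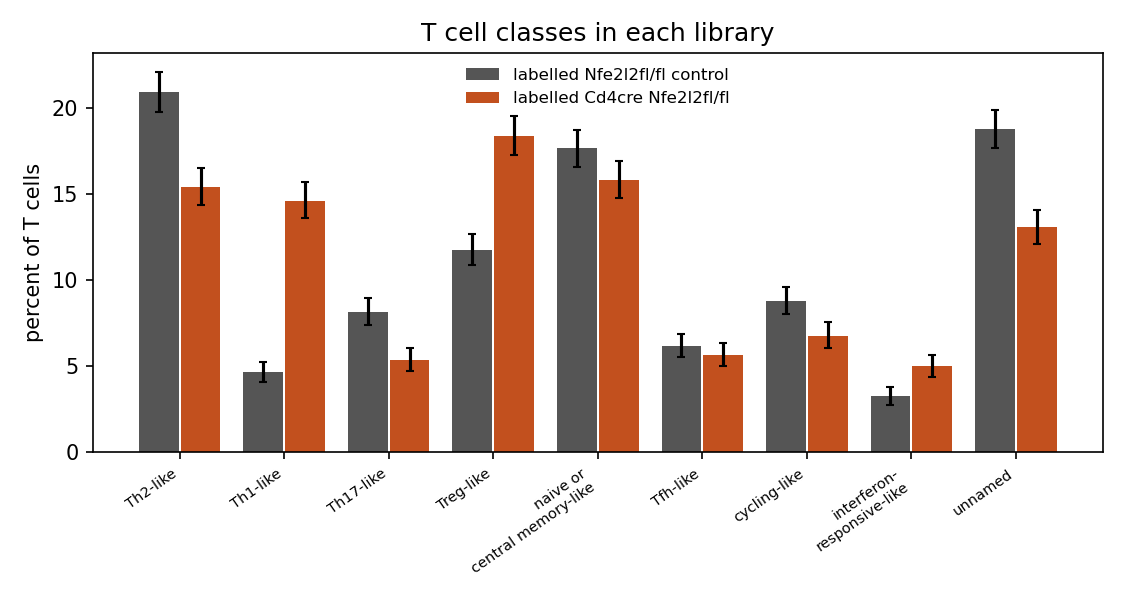
Percent of T cells (vertical axis) in each T cell class for the library labelled control (grey, 4909 T cells) and the library labelled Cd4cre (orange, 4510 T cells). Bars are single libraries with Clopper-Pearson 95% intervals. Th2-like cells were 20.9% and 15.4%, a direction that reversed to a difference of 1.35 points with genes scaled within each library, and Th1-like cells were 4.62% and 14.6%.

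The series title speaks of the polyfunctionality of Th2 cells, so type 2 cytokine genes were compared within the Th2-like class. Il4, which drives IgE switching, was at 326 CPM (interval 315 to 337) in the control library and 245 CPM (233 to 259) in the library labelled Cd4cre, a log2 ratio of -0.41 (-0.50 to -0.32). Il13, which acts on airway epithelium and mucus, was at 3102 and 2653 CPM (log2 -0.23, -0.25 to -0.20). Il5, the eosinophil growth factor, was at 387 and 348 CPM (log2 -0.15, -0.23 to -0.07), and Areg, which encodes amphiregulin, at 2791 and 2397 CPM (log2 -0.22, -0.25 to -0.19). Il10 was at 404 and 392 CPM. Csf2, the gene of the growth factor GM-CSF, had 24 and 109 UMIs, held by 18 cells in each library, so its level rests on few cells. Over the list, 8 of 10 measured genes were lower, with a median of -0.18 (-0.41 to 0.01) at percentile 0.81. That median was 0.03 at resolution 2 and -0.57 with genes scaled within each library, so its direction and size depended on which cells were called Th2-like. Its interval included 0 in 11 of 16 alternatives.

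The polyfunctional share of Th2-like cells was 39.0% (396 of 1016, interval 36.0 to 42.1) in the control library and 33.6% (229 of 682, 30.04 to 37.3) in the library labelled Cd4cre after thinning to 2000 UMIs. The difference was -5.40 points (-10.1 to -0.64). Thinning left out 11 and 13 shallower cells, and unthinned shares were 66.5% and 58.4% at median depths of 8280 and 7238 UMIs. A UMI of Il13 was seen in 73.5% and 68.3% of thinned Th2-like cells, of Il4 in 26.4% and 21.7%, and of Il5 in 26.4% and 23.6%. As background, naive or central memory-like cells gave 1 of 835 and 0 of 680 (3 cells would be 0.441%), at median depths of 4335.5 and 4165.5 UMIs. B cell-like cluster 16 gave 0 of 15 and 0 of 37, too few to set a low limit. Macrophage-like cluster 7 gave 0 of 162 and 4 of 359 (1.11%), with a UMI of Il13 in 3.70% and 2.51% of its thinned cells. The difference kept its sign in all 13 alternatives, from -1.93 points with the UMI gate to -17.5 points with genes scaled within each library. In 10 of these 13 the counting interval included 0, so the lower share is not separated from counting error under most choices.

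Of 8 metabolic and stress lists in Th2-like cells, 4 had medians somewhat below 0 in the library labelled Cd4cre. The typical gene in these cells was itself at -0.039 (median over 7110 genes), so part of each such median is shared by genes at large. Glycolysis had 13 of 18 genes lower, with a median of -0.21 (-0.29 to 0.04) at percentile 0.01. This interval included 0, as it did in all 16 alternatives. Pkm, the last enzyme of the pathway, was at 806 and 656 CPM, and aldolase Aldoa at 1235 and 1028 CPM. Ldha was at 1816 and 1602 CPM, Gapdh at 907 and 932 CPM, and hexokinase Hk2 was higher at 18.9 and 27.3 CPM. Nuclear genes of oxidative phosphorylation had 62 of 76 lower, with a median of -0.09 (-0.11 to -0.05) at percentile 0.57, as in Atp5g3 (948 and 828 CPM). That median was -0.04 both with the UMI gate and with genes scaled within each library. The 13 mitochondrial genes of the same pathway had 12 higher and a median of 0.06 (0.01 to 0.15), within the range of random lists (percentile 95.2). Among them mt-Atp8 was at 605 and 1066 CPM, and mt-Atp6 was the 1 lower gene (3419 and 2762 CPM). A rise of at least 1.5-fold in 1 of the 13 genes was also seen in Treg-like, Th17-like and Th1-like cells. Such a rise was thus not particular to Th2-like cells. The tricarboxylic acid cycle list was lower in 18 of 20 genes (median -0.14, -0.21 to -0.12, percentile 1.74), with Mdh1 at 501 and 412 CPM. Genes of lipid uptake, PPARG and fatty acid oxidation were lower in 21 of 27 (median -0.16, -0.25 to -0.05, percentile 1.49). Both medians lie just outside the 95% range of random lists, which reaches -0.14 and -0.15. Among them were Pparg, a lipid-sensing nuclear receptor (126 and 92.4 CPM), and the lipid droplet gene Plin2 (206 and 157 CPM). Sterol synthesis (median -0.02), amino acid transport and mTORC1 (median 0.00, with 10 of 23 higher) and the integrated stress and unfolded protein response (median 0.02) were near 0. The cell cycle list, which is not metabolic, was lower by more than any of these (median -0.25, -0.37 to -0.06, 24 of 27 lower, percentile 0.08). Its direction turned when all variable genes were used for clustering.

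**Figure D3:**
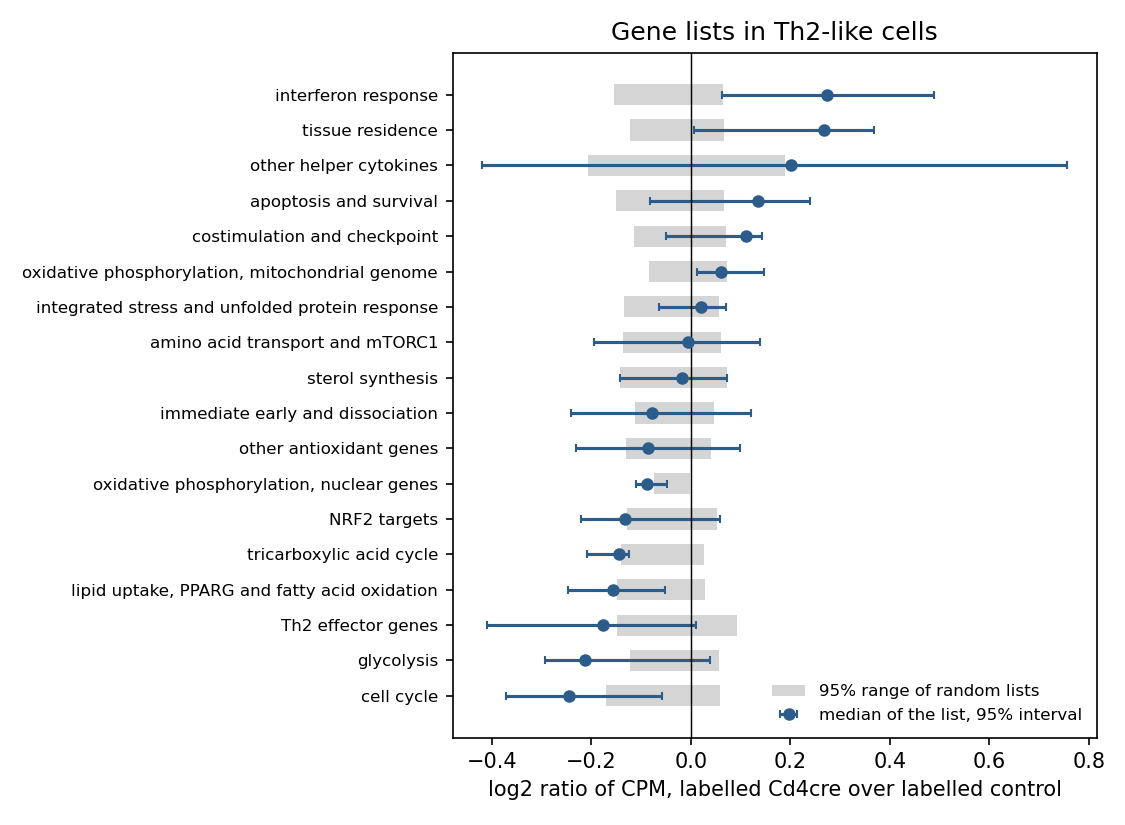
Median log2 ratio of CPM in Th2-like cells (horizontal axis, labelled Cd4cre over labelled control) for the 18 gene lists. Points are medians over list members with order-statistic 95% intervals, and grey bands are the 95% range of random expression-matched lists. Glycolysis lies at -0.21 and the interferon response at 0.27.

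Over all T cells, the type 2 list was lower in 9 of 10 genes (median -0.44, -0.77 to -0.17), with Il4 at 118 and 69.0 CPM and Il13 at 1090 and 695 CPM. The lipid, PPARG and fatty acid oxidation list was lower in 25 of 30 (median -0.17), with Pparg at 60.3 and 34.5 CPM. Glycolysis (median -0.11), nuclear oxidative phosphorylation (median -0.05), the tricarboxylic acid cycle (-0.14, 20 of 20 lower), sterol synthesis (-0.15) and the cell cycle (-0.23, 27 of 28 lower) also had medians below 0. Of these, the glycolysis interval included 0 (-0.26 to 0.03), and both glycolysis (percentile 2.89) and nuclear oxidative phosphorylation (percentile 10.2) lay within the range of random lists. The typical gene in T cells was itself at -0.031. Values over all T cells carry the class shares given above as well as levels within classes. The other helper cytokines had a median of 0.09, with Ifng at 41.3 and 85.8 CPM and Il17a at 924 and 715 CPM. The interferon response list was higher in 23 of 23 genes (median 0.62, 0.46 to 0.97), as in Ifit3 (10.3 and 30.3 CPM) and Isg15 (202 and 306 CPM). This did not hold in every class, with medians of -0.03 in Th1-like cells, -0.04 in cluster 2, 0.09 in Th17-like cells and 0.78 in cycling-like cells. Tissue residence (median 0.20), costimulation and checkpoint genes (0.10) and apoptosis and survival genes (0.10) had medians above 0, all 3 with intervals that included 0. At percentiles 100, 99.96 and 99.93, all 3 lay above the range of random lists. Tissue residence was at 0.27 (0.01 to 0.37) in Th2-like cells, but at -0.01 in Treg-like and -0.04 in Th17-like cells. Immediate early and dissociation genes had a median of -0.03, although Ier3 was at 88.4 and 43.3 CPM.

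By the size rule, the genes most above the control in T cells of the library labelled Cd4cre began with the cytotoxic protease Gzma (27.1 and 242 CPM, log2 3.16), the chemokine Ccl5 (326 and 1924 CPM, log2 2.56) and Nfe2l2. After these came Hopx (149 and 288 CPM), the inhibitory receptor Klrg1 (46.4 and 95.5 CPM), Ifng, the class I genes H2-Q6 (129 and 245 CPM) and H2-Q7 (381 and 656 CPM), Gimap7, and the interferon-induced Ifit1 (27.9 and 59.6 CPM), Rtp4 and Cxcl10. Gzma, Ccl5 and Ifng are among the leading genes of the Th1-like cluster, whose share was larger in that library. The lowest began with Ier3, Il4, Pparg and Il13, and went on with Gsn (79.1 and 50.3 CPM), the mTORC1 inhibitor gene Ddit4 (226 and 150 CPM), the leukotriene B4 receptor gene Ltb4r1 (160 and 111 CPM), Igfbp7, Pdcd1, which encodes PD-1 (417 and 300.1 CPM), Lpcat3, Ramp1 (463 and 342 CPM) and Oxsr1. Igfbp7 and Ier3 mark or lead the Th2-like cluster.

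Within Th2-like cells the same rule put Nfe2l2 highest (26.3 and 169 CPM, log2 2.69, 2.48 to 2.89). It was followed by the interferon-induced Ifi27l2a (1234 and 2506 CPM, log2 1.02, 0.99 to 1.06), Ccrl2 (23.8 and 50.7 CPM), H2-Q6, Ramp3 (46.9 and 88.1 CPM), Traf4, Polr2l, the TNF family ligands Tnfsf8 (288 and 472 CPM) and Tnfsf11, which encodes RANKL (164 and 261 CPM), H2-Q7, Rnf19b and Rnaset2a. Penk, the proenkephalin gene, was lowest (73.0 and 19.1 CPM, log2 -1.93, -2.24 to -1.64). Ddit4 (256 and 148 CPM), Dapk3, the chemokine Cxcl3 (220 and 152 CPM), Gnpda1, Smco4 (763 and 548 CPM), Ier3, Gsn, Sash3, Lman1 and Ppil1 were also lower. At resolution 2, where fewer cells were called Th2-like, Penk was higher (log2 2.88) and Cxcl3 was at 0.13. Cyp11a1 also met the rule but is one of the class's own markers and is not read as a result.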

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

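All of the tests in this part were chosen after the result was seen. Every direction below depends on library labels that the Nfe2l2 counts neither bear out nor contradict.

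Nfe2l2 was higher in T cells of the library labelled Cd4cre (log2 2.45). A different mix of T cell types is argued against by the lowest ratio over 8 T cell classes and clusters, 1.74 (interval 1.35 to 2.15, in Th1-like cells). RNA from macrophage-like cluster 7 cannot account for the T cell level in the library labelled Cd4cre, since Nfe2l2 was lower in that cluster. The marker test thus adds nothing for cluster 7, whatever its outcome. In it, 6 abundant macrophage markers reached a median of 0.241% of their cluster 7 level in T cells, with 3.33% for Ctss as the highest. Cluster 6, where Nfe2l2 was above its T cell level, was not compared. Exchanged labels stay open, since the NRF2 targets that would show them had a median of -0.044 (-0.17 to 0.04) with members going both ways. Nqo1 in T cells (-1.50, -2.61 to -0.51) and the list in Th2-like cells (-0.13, -0.22 to 0.06, percentile 2.17) run the way of the labels. In naive or central memory-like cells the list does too (-0.16, -0.25 to -0.01, 18 of 25 lower). At percentile 2.575 it lay just within the range of random lists there. The list was above 0 in Th1-like cells (0.08) and cluster 6 (0.30). Its lowest percentile was in macrophage-like cluster 7 (-0.20, -0.32 to -0.02, percentile 0.19), outside the T cells. An effect of Cd4cre on Nfe2l2 transcripts, such as counts from a transcript that lacks some exons, also stays open. Cluster 6, which is not T cells, differed by 0.84 (0.44 to 1.26), while cluster 7 differed by 0.18. Dendritic cell-like cluster 12, led by Ly6d and Siglech, differed by 1.75. Whether Cd4cre acts in those cells was not tested, so their value decides neither way.

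Interferon response genes were higher in the library labelled Cd4cre, over all T cells (median 0.62) and in some cells beyond them, but not in Th1-like cells (-0.03, 9 of 21 higher), cluster 2 (-0.04) or clearly in Th17-like cells (0.09, -0.17 to 0.30). Outside the T cells, the median was 0.73 (0.17 to 1.34) in macrophage-like cluster 7 and 1.03 (0.72 to 1.56) in endothelium-like cluster 13. In cluster 6, whose border with cluster 7 was not tested, the median was 0.29 (-0.10 to 0.90). Whether Cd4cre acts in these clusters was not tested. These values thus cannot decide whether the difference was limited to cells in which Cd4cre acts. A larger interferon-responsive cluster alone is argued against by Treg-like cells, where the median was 0.61 (0.23 to 1.07). The Treg-like cluster itself held 4 interferon-responsive markers. A larger share of interferon-responding cells within it was thus not separated from a higher level per cell. RNA from macrophages was first tested by the ratio of macrophage markers in Treg-like cells, which could not decide, with 5 measured markers and a median of 0.0638. A second test, run because the first could not decide, compared levels. The markers reached a median of 0.143% of their cluster 7 level in Treg-like cells (up to 5.46%), against 61.8% computed as needed for the summed interferon list. The outcome was fixed, because that list summed to 1757 CPM in cluster 7 of the library labelled Cd4cre. This is below its 2837 CPM in Treg-like cells of the control library. Added RNA of cluster 7 could thus not raise the sum, whatever its amount. RNA of cluster 6 was not compared. A difference in exposure between the mice or libraries stays open and untested.

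The Th1-like share was higher (14.6% against 4.62%) and the Th2-like share lower (15.4% against 20.9%) in the library labelled Cd4cre. A depth gap as the whole cause is argued against by thinning cells to 2000 UMIs before clustering. After this the Th2-like difference was -3.88 points (-5.34 to -2.43) and that of the Th1-like share of T cells 9.52 (8.41 to 10.6). Cells under 2000 UMIs were left out first, 265 in the control library and 656 in the other. These shares thus cover the deeper cells only. A single expanded T cell clone is argued against as the whole cause of the Th1-like part, since without cells with a leading Trbv20 the difference was 5.80 points (4.67 to 6.93; shares of 4.67% and 10.5%), and of the Th2-like part, where it was -5.00 (-6.63 to -3.36). The Th2-like part does depend on the clustering, with a difference of 1.35 points when genes were scaled within each library. Differences of genotype, strain, mouse or handling are confounded with 1 library per group and stay open.

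Some signals lie in cells or transcripts outside the main comparisons or go opposite ways between classes, and are given as values. Cluster 6, outside the T cells, took 16.4% of all cells in the library labelled Cd4cre and 1.90% in the control library. Trbv20, a T cell receptor beta V gene, led in 37.6% (228 of 607, interval 33.7 to 41.5) of Th1-like cells with a beta chain in the library labelled Cd4cre and in 3.06% (6 of 196, 1.13 to 6.54) in the control library. Of the 42 genes named in T cells or Th2-like cells, 3 lay beyond 1.5-fold with their counting interval in opposite directions in 2 of the 8 classes and clusters, each with at least 50 UMIs, and none of these differences was tested. Genes named only in other classes, and smaller opposite differences such as that of Cxcl3 (log2 -0.53 in Th2-like cells and 0.58 in cluster 2), are not in this count. Gzma had 0 UMIs and 37.8 CPM in Tfh-like cells (log2 of at least 5.13 at a floor of 3 counts over the class). It was at 42.9 and 0.514 CPM in Th17-like cells (log2 -6.39, -11.7 to -3.88, from 1 UMI in the library labelled Cd4cre). The difference of 11.5 applies the floor to the 0 only. The 1 UMI, which is under that floor, was used as it stands, so the size of the difference is not reliable. Penk was at 64.6 and 159 CPM in Th17-like cells and 73.0 and 19.1 CPM in Th2-like cells, a difference of 3.24, but at resolution 2 Penk in Th2-like cells turned to 2.88, the same direction as in Th17-like cells. Tnfsf8 was at 288 and 472 CPM in Th2-like cells and 95.5 and 47.3 CPM in Th1-like cells, a difference of 1.73.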

How the results depend on the processing

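The 8 main results were recomputed under 19 alternatives, 15 planned and 4 chosen after seeing the data, giving 105 values, of which 102 kept their sign, 95 stayed within the interval of the reported value, 9 moved beyond it and 1 reversed, meaning a changed sign where the interval of the reported value excluded 0. Of the 1039 values of 82 other results, 887 stayed within the interval, 145 moved and 7 reversed. No library was left out, since each group has 1. With genes scaled within each library before clustering, the Th2-like share difference reversed to 1.35 points, the Th2 effector median was -0.57, the polyfunctional difference -17.5 points and the oxidative phosphorylation median -0.038. At resolution 2 the Th2-like share difference was -2.15 points and the Th2 effector median 0.035, and in Th2-like cells Penk (2.88), Cyp11a1 (0.97) and Cxcl3 (0.13) reversed. Thinning every cell before clustering gave a Th2-like difference of -3.88 points, and the UMI gate an oxidative phosphorylation median of -0.043. Nfe2l2 was 2.28 with T cell clusters brought to the same makeup and 2.26 with each cell weighted equally. The Th17-like share difference reversed to 0.89 points with the highest doublet scores removed, 0.91 with thinned cells and 18.6 with genes scaled within each library, and the cell cycle median in Th2-like cells to 0.010 with all variable genes. The cells that carried a name changed with the setting. At resolution 2 a T cell cluster with 6 Th2 markers stayed unnamed. With genes scaled within each library, a further cluster with 3 Th17 markers was named Th17-like. Such changes of sign thus do not compare the same cells, and how much of them the naming accounts for was not tested. The other changed signs were in the NRF2 target median (1 of 12) and the Th2 effector median (1 of 16), whose reported intervals included 0. The polyfunctional difference kept its sign in 13 of 13 alternatives, but its interval included 0 in 10. The Treg-like difference stayed between 5.49 and 8.04 points in 11 alternatives, and glycolysis between -0.24 and -0.10 in 16. Depth limits genes such as Nqo1, with 50 UMIs or fewer over both libraries.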

Other observations

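Other T cell classes also differed in named genes. In Treg-like cells the chemokines Ccl3 (67.4 and 5.48 CPM, control library first) and Ccl4 (120 and 45.3 CPM) and the surface protein gene Ly6a (2291 and 1317 CPM) were lower in the library labelled Cd4cre. So were Il13 (142 and 58.5 CPM) and Igfbp7 (70.0 and 35.3 CPM), which lead or mark the Th2-like cluster, and the Th2 effector list had a median of -0.92 (-1.32 to 1.02, 5 of 7 lower). Ccl5 (201 and 453 CPM) and the interferon-induced Ifi213 (21.2 and 52.9 CPM) were higher. The rise of Ccl5 was not particular to Treg-like cells. It was at 34.2 and 95.5 CPM in naive or central memory-like, 24.2 and 125 CPM in Tfh-like and 92.3 and 399 CPM in cycling-like cells. Ccl5 leads the Th1-like cluster, and how its larger share and remaining doublets bear on these values was not tested. In Th17-like cells Il17a was at 4034 and 4039 CPM, a gene chosen after its values were seen, while Cxcl2 (44.8 and 142 CPM) and the stress factor gene Atf3 (21.3 and 59.1 CPM) were higher and Ccl1 (112 and 25.2 CPM) and Tnf (109 and 56.0 CPM) lower. In naive or central memory-like cells Il17a was at 226 and 60.6 CPM, but in few cells (33 of 866 and 21 of 714), and after thinning its share of cells was 2.40% and 2.35%. In Th1-like cells Klrg1 (16.6 and 136 CPM) and the chemokine receptor gene Cx3cr1 (24.4 and 79.2 CPM) were higher and Xcl1 (85.8 and 7.57 CPM), Fcer1g (141 and 19.9 CPM) and Tyrobp (72.2 and 14.2 CPM) lower. These last 3 are expressed by NK and innate lymphoid cells, and the makeup of this cluster differed between the libraries, including its Trbv20 share (3.06% and 37.6%), so the values are those of the cluster as a whole.

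In macrophage-like cluster 7, class II genes were higher in the library labelled Cd4cre, with H2-Eb1 at 126 and 523 CPM, H2-Aa at 303 and 885 CPM and H2-Ab1 at 327 and 927 CPM. The same genes lead cluster 6, which took 1.90% and 16.4% of all cells, and how the border between the clusters bears on these values was not tested. The interferon-induced chemokine Cxcl9 had 5 and 226 UMIs (log2 4.26, 3.02 to 5.90), and the platelet factor gene Pf4 was lower (1035 and 374 CPM).

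The following genes were chosen after their values were seen. Cd4 was higher in the library labelled Cd4cre in 8 of 8 T cell classes and clusters, with log2 ratios from 0.24 to 0.66. In T cells Chchd2 was at 360.2 and 477 CPM and Polr2l at 44.3 and 68.5 CPM. Of 117 Th1-like cells with Trbv20 and both receptor chains in the library labelled Cd4cre, 80 (68.4%) carried Trav9-2 as the leading alpha V gene, against 1.76% of the other Th1-like cells there. Xist, transcribed from the inactive X chromosome, was at 330.3 and 338 CPM in T cells, and Ddx3y, on the Y chromosome, had 0 UMIs in both libraries.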
